A study of Mus musculus with 6 samples.

How the data were processed

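Binding of Grhl3 was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse skin. The labels describe 6 libraries. Of these, 4 were made with a custom Grhl3 antibody and 2 are input controls without antibody. The Grhl3 libraries are 2 replicates from whole skin of E16.5 embryos, 1 from adult epidermis at day 4 of a depilation experiment and 1 from adult epidermis of an imiquimod experiment. Per the labels' protocols, adult epidermis was freed from dermis with dispase before fixation, 28 µg of sonicated chromatin went into each Grhl3 precipitation, and the libraries were sequenced as single-end reads of 50 cycles. Embryonic and adult samples therefore differ in tissue (whole skin against epidermis) as well as in age and treatment.

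Per the submitters' processing notes, the tools include Bowtie 0.12.7 and bedtools 2.11.2 and the genome build is mm9. The caller's settings and the use of the input libraries are not given in the sources used here. The E16.5 and depilation lists, as deposited, give for each peak a position and a peak score, with peak names that begin with MACS. The score is 50 or more in every row of these lists and reaches 3100 in 2 of them, and what it measures is not given in the sources used here. The imiquimod list has another layout. Per the file headers, it gives the authors' count of tags in each peak, a fold enrichment over the caller's background and a false discovery rate (FDR) in percent. The header of its score column is lost to a spreadsheet error in the deposited list, and its values, from 52.35 to 249.45, were read as the same kind of score as in the other lists. That reading was not checked by another source. No peak in it has an FDR above 10%. Per the labels each list belongs to 1 library, so the replicates were compared as lists. The labels do not say whether the E16.5 replicates come from separate animals. Read totals of the libraries were not used here, so the depth behind each list is unknown. Numbers of peaks, and shares of peaks found in another list, depend on depth and on each list's threshold. Exact 95% binomial intervals (Clopper-Pearson) cover counting error only, and treat neighbouring peaks as independent.

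Positions are given 1-based on mm9. BED starts were raised by 1 bp, and the imiquimod positions were already 1-based, since end minus start plus 1 equals the length column in every row. Peaks counted as shared when they overlapped by at least 1 bp. The E16.5 reproducible set holds the replicate 1 peaks overlapped by a replicate 2 peak. It stood for E16.5 in every comparison with adult epidermis. Regions were made by merging the E16.5 reproducible, depilation and imiquimod lists where peaks overlapped or touched. The overlap of 2 lists was set against 1000 placements in which one list was shifted circularly by a random offset within each chromosome, over the span that peaks of any list cover (a circular permutation). The p is one-sided, and 0.001 is the smallest that 1000 placements can give. Such placement ignores that peaks of any factor favour open chromatin, so a high fold over placement does not by itself show binding of one factor. If the depilation and imiquimod lists were called against the same adult input, they also share its chance values. Shares of one list found in either of 2 others were compared with an exact McNemar test (two-sided, Benjamini-Hochberg adjustment over 3 comparisons). With 1 library per adult condition these tests compare peak lists, with the peak as the unit, and not the conditions. Shares on chromosome X were compared with Fisher's exact test (two-sided, adjusted over 3 comparisons). The scores of shared peaks were related by rank with 100000 permutations, and the percentiles of 2 sets of E16.5 regions were compared with 10000, both two-sided. The percentile of a peak is its score rank within its own list, and that of an E16.5 region is the mean of its percentiles in the 2 replicates. The score of an E16.5 region is that of replicate 1. It was used for the score deciles, the score relations and the choice of the best scoring E16.5 regions in the alternatives. Where a region held several peaks of a list, the highest value was used.

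The placement test was tested on simulated data at the sizes of the depilation and E16.5 replicate 2 lists, with peaks at uniform random positions. With no planted overlap, 2 of 50 simulated pairs of lists gave a p of 0.05 or less. With 200 planted peaks, the excess over placement was 199.1 ± 2.88 (SD, 50 simulated pairs). The deposited lists hold denser clusters of peaks than such simulated lists, so these rates need not hold for them. The overlap of these 2 lists was checked against bedtools 2.31.1, and both gave 1645 peaks. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

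The regions named in the text were chosen by a rule fixed before the data were examined. That rule also named genes, a part not run here. The regions are the 10 in all 3 conditions with the highest mean score percentile, the 5 best scoring regions found in each condition alone, and the 3 best scoring peaks of each list. The alternatives were fixed at the same time, apart from 2 added after the data were seen, which left out the peaks scoring above the imiquimod maximum, and left out chromosomes X and Y together with a run of imiquimod peaks on chromosome 2. The overlaps, their placement tests and the regions by condition were planned as well. The McNemar tests, the placement of regions in all 3 conditions, the shares by score decile and by replicate, the comparisons of scores, the shares on chromosome X and the run on chromosome 2 were added after the data were seen. The other alternatives changed the overlap that counts as shared, the peaks admitted by score or width, the placement, and the E16.5 set. Distances to genes, 12 lists of genes set up beforehand and the Grhl motif were not analysed here, because they need an mm9 annotation or sequence and the gene table at hand is of another build. No gene is therefore named beside a region.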

Results

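Grhl3 is a transcription factor of the grainyhead-like family that acts in the formation of the epidermal barrier. The series mapped its binding in developing skin and in 2 models of injury to adult skin, as its title states. One model is depilation, the removal of hair, a physical injury. The other is imiquimod, an activator of Toll-like receptors that causes a psoriasis-like inflammation when applied to skin. The peak lists of 4 Grhl3 libraries were compared, 2 replicates from E16.5 whole skin and 1 each from epidermis at day 4 of depilation and from imiquimod-treated epidermis. The comparisons ask which Grhl3 regions recur between the E16.5 replicates, which of them are found again in injured adult epidermis, and which the 2 injuries share.

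The E16.5 lists held the most peaks, 11619 in replicate 1 and 9685 in replicate 2. The imiquimod list held 7974 peaks and the depilation list 4820. Peaks of E16.5 replicate 1 were the widest, with a median of 445 bp, against 232 bp in replicate 2, 204.5 bp after depilation and 277 bp after imiquimod. Together the peaks of E16.5 replicate 1 covered 5.99 Mb, those of replicate 2 covered 2.83 Mb, those of the depilation list 1.14 Mb and those of the imiquimod list 2.42 Mb. An imiquimod peak held a median of 29 tags (interquartile range 22 to 42) at a median fold enrichment of 6.65. Tags per peak are known for this list alone, and library depth is unknown for all of them.

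The best scoring peaks of E16.5 replicate 2 and of the depilation list fell on the same places, on chromosomes 17 and 2, and those of E16.5 replicate 1 lay elsewhere. On chromosome 17, a peak of nearly 4 kb had the highest score in 2 lists. It lay at 39979912 to 39983765 in E16.5 replicate 2 and at 39979927 to 39983720 after depilation. Its score was 3100 in both, the highest in any list, and after depilation a chromosome 2 peak tied with it. Scores stop at 3100, so equal scores there need not mean equal strength. A second peak of E16.5 replicate 2 lay beside it, at 39984447 to 39985800 with a score of 1051.65. On chromosome 2, the peak at 98506374 to 98507518 scored 3100 after depilation and its counterpart at 98506372 to 98507523 scored 1293.41 in E16.5 replicate 2. The depilation peak at 98502352 to 98503189 on the same chromosome scored 2952.32. The best peaks of E16.5 replicate 1 lay on chromosome Y at 2855175 to 2861520, with a score of 1588.84, on chromosome X at 166434797 to 166436276, with 980.23, and on chromosome 10 at 25999660 to 26000310, with 911.37. Each of these 9 peaks was overlapped in both E16.5 replicates and after depilation, and none was overlapped by an imiquimod peak. No peak was left out here for lying in a repeat or for high signal in input. A high score that recurs between lists therefore does not by itself show Grhl3 binding at these places. The best imiquimod peaks were at 16786275 to 16787002 on chromosome 6 (score 249.45), 57831706 to 57832356 on chromosome 1 (249.32) and 63936189 to 63936687 on chromosome 2 (247.61). Of these 3, the chromosome 1 peak alone was overlapped by a peak of each other list.

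Chromosome X carried fewer peaks in the imiquimod list than in any other. It held 25 peaks there, 0.314% of the list (95% interval 0.203 to 0.462). Its share was 1.29% (1.09 to 1.51) in E16.5 replicate 1, 1.42% (1.2 to 1.68) in replicate 2 and 1.18% (0.897 to 1.53) after depilation. The depilation share was 3.77 times the imiquimod share (Fisher's exact test, adjusted p = 6.3e-09), and the E16.5 shares were 4.12 and 4.54 times as high (adjusted p = 6.32e-14 and 1.78e-15). Peaks on X were sparse in every list. Their density per Mb was 0.93 in E16.5 replicate 1, 0.85 in replicate 2, 0.35 after depilation and 0.15 after imiquimod. The lowest density of an autosome was 3.73, 2.85, 1.55 and 2.66 in the same order. Chromosome Y held 37, 68 and 14 peaks in E16.5 replicate 1, E16.5 replicate 2 and the depilation list. The imiquimod list held 0 peaks there.

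The E16.5 replicates shared a minority of their peaks, and these were the stronger ones. Of the replicate 1 peaks, 3771 were overlapped by a replicate 2 peak, or 32.5% (95% interval 31.6 to 33.3). In the other direction, 4035 replicate 2 peaks were shared, or 41.7% (40.7 to 42.7). The shared replicate 1 peaks were 100.02 times as many as after random placement, whose mean was 37.7 and highest value 76 (circular permutation p = 0.001). Among replicate 1 peaks in the lowest decile of score, 6.45% (5.11 to 8.02) recurred in replicate 2, and in the highest decile 75.6% (73.0 to 78.0) did. For replicate 2 peaks the corresponding shares were 19.9% (17.4 to 22.6) and 68.2% (65.2 to 71.1). Across the shared peaks, which are not independent replicates, the scores of the replicates were weakly related (Spearman's rho = 0.31, Pearson's r of log10 scores = 0.35, permutation p = 1e-05, the smallest that 100000 permutations can give).

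**Figure D1:**
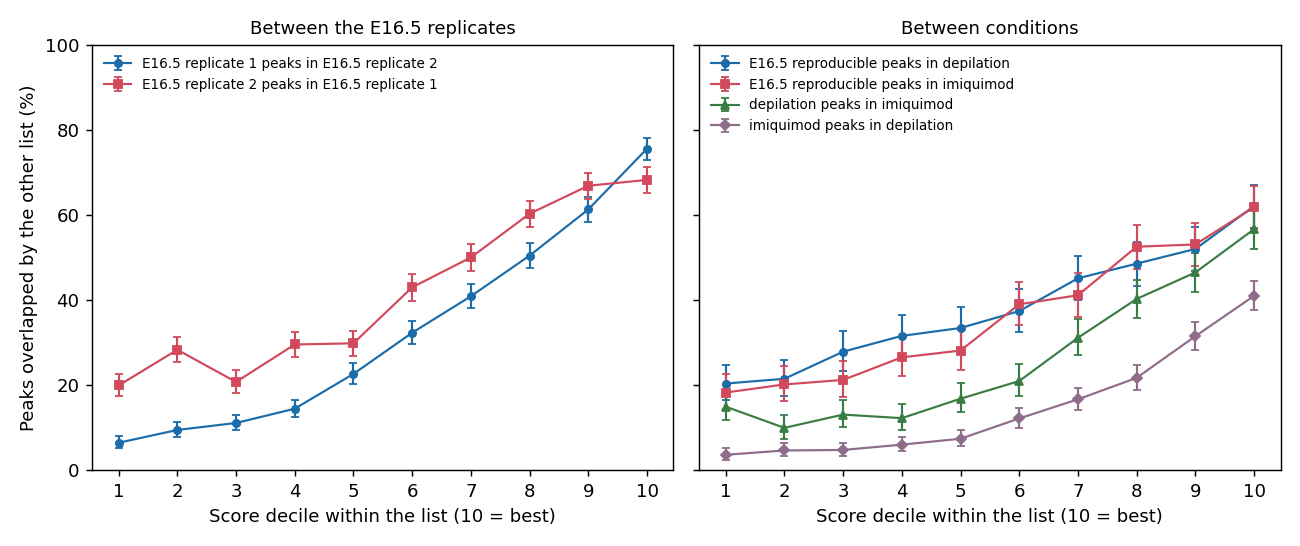
Share of peaks overlapped by another list (percent, vertical axis) in each score decile of the list (horizontal axis, 10 is the best), for the E16.5 replicates at left and for pairs of conditions at right. Points are shares and bars are exact 95% binomial intervals; the highest decile has a higher share than the lowest in each comparison drawn, for E16.5 replicate 1 with 75.6% against 6.45%.

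Replicate 1 peaks that recurred in replicate 2 were found more often in adult epidermis than those that did not. Of these 3771 regions, 38.0% (36.4 to 39.5) carried a depilation peak and 36.2% (34.6 to 37.7) an imiquimod peak. Of the 7848 replicate 1 peaks missing from replicate 2, 9.96% (9.31 to 10.6) carried a depilation peak and 9.70% (9.05 to 10.4) an imiquimod peak. Of the 5650 replicate 2 peaks missing from replicate 1, 2.94% (2.51 to 3.41) and 2.106% (1.75 to 2.52) did. The recurring replicate 1 peaks were also wider and better scored. Their medians were 664 bp and 103.08, against 445 bp and 69.06 for all replicate 1 peaks. The shares were not adjusted for width or score.

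Between embryonic skin and depilated epidermis, 1432 of the 3771 E16.5 reproducible regions were shared, 193.4 times the mean of 7.40 after random placement (circular permutation p = 0.001). Seen from the adult side, 1611 of 4820 depilation peaks, or 33.4% (32.1 to 34.8), lay on E16.5 reproducible regions. With replicate 1 as the E16.5 set this was 50.6% (2439 peaks), and with replicate 2 it was 34.1% (1645 peaks). The share of E16.5 regions with a depilation peak rose with their replicate 1 score. It went from 20.4% (16.4 to 24.8) in the lowest decile to 62.1% (57.0 to 67.0) in the highest. The adult condition has 1 library, so this overlap has no replicate check on that side. Without E16.5 replicate 2, the peaks of replicate 1 shared with depilation numbered 2214, or 19.1% of that list. The fold over placement was then 127.7, against 147.1 without replicate 1 and 106.1 with the union of the replicates.

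Between embryonic skin and imiquimod-treated epidermis, 1364 of the 3771 E16.5 regions were shared, 109.7 times the mean of 12.4 after random placement (circular permutation p = 0.001). From the adult side, 1441 of 7974 imiquimod peaks, or 18.1% (17.2 to 18.9), lay on E16.5 reproducible regions. With replicate 1 as the E16.5 set this was 27.9% (2221 peaks), and with replicate 2 it was 18.6% (1487 peaks). The share of E16.5 regions with an imiquimod peak again rose with their replicate 1 score. It went from 18.3% (14.5 to 22.5) in the lowest decile to 61.8% (56.7 to 66.7) in the highest. The imiquimod list held no peak scoring above 249.45, whereas 163, 44 and 36 peaks of E16.5 replicate 1, E16.5 replicate 2 and the depilation list did. Without E16.5 replicate 2, the peaks of replicate 1 shared with imiquimod numbered 2125, or 18.3% of that list. The fold over placement was then 69.3, against 80.9 without replicate 1 and 55.8 with the union of the replicates. The FDR of the imiquimod list fell to 2.9% at a score of 112.74 and rose again to 10% at the highest score.

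**Figure D2:**
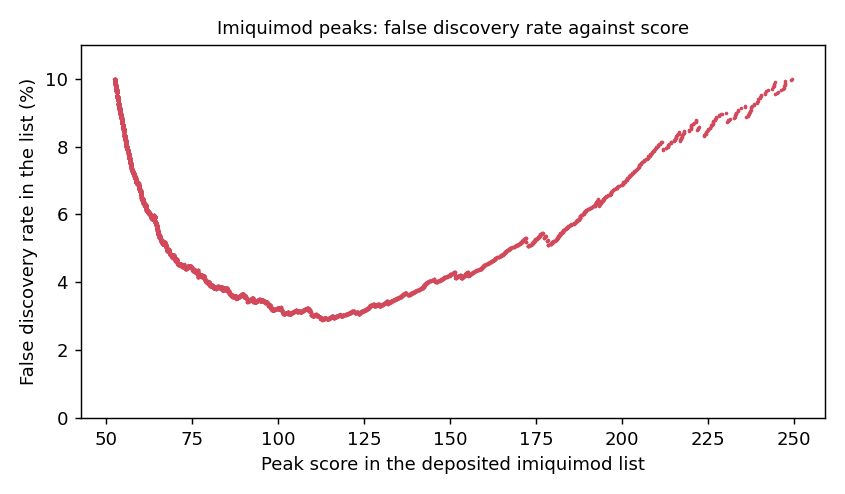
False discovery rate (percent, vertical axis) against peak score (horizontal axis) for the 7974 peaks of the imiquimod list, each point a peak. The rate falls from 10% at a score of 52.35 to 2.9% at 112.74 and rises back to 10% at 249.45, where the list ends.

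Each adult list shared fewer of its peaks with the other adult list than with E16.5 regions. Set against random placement in the main setting, this order held for depilation and turned for imiquimod. Depilation peaks lay on E16.5 regions 218 times and on imiquimod peaks 152 times as often as after placement. Imiquimod peaks lay 115.4 times as often on E16.5 regions and 144.3 times on depilation peaks (circular permutation p = 0.001 in each). The differences between these folds were not tested. Counted from E16.5, the depilation fold was 147.1 without replicate 1, 127.7 without replicate 2 and 106.1 with their union, below 152. It was also lower with the better scoring 50% (291.6 against 306) and the 1000 best peaks (332.9 against 586.4), and higher in the other alternatives. The imiquimod order failed to turn only with centres within 500 bp (111.9 against 88.7). Of the depilation peaks, 1265 carried an imiquimod peak, or 26.2% (25 to 27.5), against a mean of 8.32 after random placement. Of the imiquimod peaks, 1192 carried a depilation peak, or 14.9% (14.2 to 15.8). Depilation peaks lay on E16.5 regions more often than on imiquimod peaks by 7.18 percentage points (exact McNemar test, adjusted p = 1.03e-21), and imiquimod peaks lay on E16.5 regions more often than on depilation peaks by 3.12 points (adjusted p = 4.76e-13). Without E16.5 replicate 2 these differences were 24.4 and 12.9 points, and without the peaks above the imiquimod maximum score 4.14 and 1.73 points. With the better scoring 50% of each list they were -1.12 points (exact McNemar p = 0.343) and 1.66 points (p = 0.0242), and with the 1000 best peaks of each list 5.9 points (p = 0.00109) and 1.30 points (p = 0.464). For E16.5 regions, the share with a depilation peak exceeded that with an imiquimod peak by 1.80 points, which did not pass the test (exact McNemar test, adjusted p = 0.0627). Of the E16.5 regions in 1 adult list alone, 52.6% (49.9 to 55.4) were in the depilation list. The difference of 1.80 points was 0.599 points without E16.5 replicate 1 and 0.766 points without replicate 2. With the better scoring 50% of each list it was -4.88 points (exact McNemar p = 0.000553).

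Merging the 3 conditions gave 13035 regions. Of these, 750 carried a peak in all 3, against a mean of 0.045 and a maximum of 2 after random placement (circular permutation p = 0.001). This placement moved both adult lists, so it also removed the overlap of each pair given above, and it tests nothing beyond them. Of the E16.5 regions with a depilation peak, 52.4% carried an imiquimod peak, against 26.3% of those without one. A further 680 were shared by E16.5 and depilation, 610 by E16.5 and imiquimod and 456 by the 2 adult lists. Regions found in 1 condition numbered 1725 for E16.5, 2740 for depilation and 6074 for imiquimod. Of the 2740 depilation regions, 600 had a peak in at least 1 E16.5 replicate, as had 511 of the 6074 imiquimod regions and 388 of the 456 shared by the adult lists. Requiring a peak in either E16.5 replicate instead of both raised the regions in all 3 to 1145 and those in E16.5 alone to 13769, and lowered those of the 2 adult lists without E16.5 to 68. Regions in E16.5 alone numbered 8385 without replicate 2 and 7354 without replicate 1, and regions of the adult lists without E16.5 numbered 110 and 437. Regions of E16.5 and depilation numbered 1107 without replicate 2, 795 without replicate 1 and 1228 with a peak in either replicate. Those of E16.5 and imiquimod numbered 1008, 684 and 1082 in the same order.

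**Figure D3:**
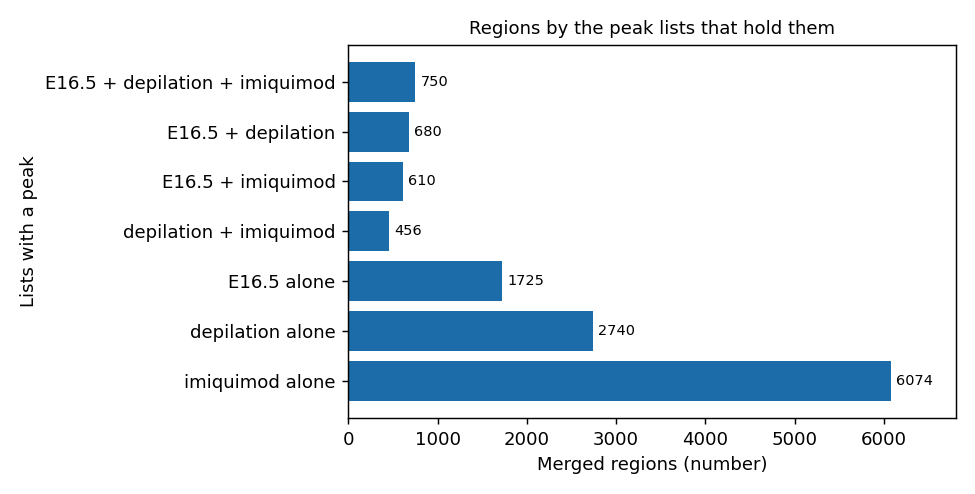
Number of merged regions (horizontal axis) by the peak lists that hold them (vertical axis), with E16.5 standing for the reproducible set; each bar is a count from 1 set of lists and has no error bar. Regions in all 3 conditions number 750, and those in the imiquimod list alone, 6074, are the most numerous.

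Regions in all 3 conditions were well scored. Their median score percentile was 79.9 among E16.5 peaks, 77 among depilation peaks and 82.1 among imiquimod peaks. In regions of 1 condition it was 62.2 for E16.5, 37.9 for depilation and 41.5 for imiquimod. E16.5 regions had to recur in both replicates, which favours high scores, and the adult regions had no such filter. The E16.5 percentiles are therefore not comparable with the adult ones. Merging makes regions of several lists wider by construction, with a median of 875.5 bp in all 3 against 551 bp in E16.5 alone, and a wider region can hold more than 1 peak of a list, of which the best counts. The E16.5 regions in both adult lists had a mean percentile 15.6 points above that of regions in neither (permutation p = 1e-04, the smallest that 10000 permutations can give, 750 against 1725 regions). In the best decile of E16.5 regions by percentile, 70 of 377 were still in neither adult list, or 18.6% (14.8 to 22.9).

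The 10 best regions in all 3 conditions lay on 5 autosomes and on chromosome X. Those with the highest mean percentile were 2 neighbours on chromosome X, at 166431860 to 166432731 and at 166426483 to 166427534. The first scored 456.06 and 225.26 in E16.5 replicates 1 and 2, 283.72 after depilation and 199.83 after imiquimod. The second scored 429.57, 350.33, 137.72 and 245.05 in the same order. Both lie near one of the best scoring peaks of the E16.5 lists. Their imiquimod fold enrichments were 6.24 and 3.82, below the median of the list, with 190 and 382 tags against a list median of 29. A high score therefore need not mean a high enrichment. Signal in the input libraries was not analysed here. All regions named here rank best by score, and were not shown to be the strongest binding sites. The best autosomal region was at 53163787 to 53164775 on chromosome 11, with scores of 322.51, 272.94, 159.98 and 192.42. Chromosome 1 had regions at 10222543 to 10223487 and at 91864729 to 91865401. The latter had the highest imiquimod fold enrichment of the 10, at 12.57, and scores of 161.19, 164.26, 119.87 and 240.18. The FDR of the imiquimod list at that last score was 9.45%. The remaining 5 were at 81523985 to 81525610 and 78744213 to 78745102 on chromosome 15, at 48035912 to 48036842 and 54766475 to 54767550 on chromosome 6, and at 124699161 to 124700125 on chromosome 5.

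The best regions in E16.5 alone lay partly on the sex chromosomes. They were on chromosome Y at 2899122 to 2901238 and 2884361 to 2887559, on chromosome X at 121268052 to 121268643, on chromosome 13 at 120281006 to 120283397 and on chromosome 8 at 81818524 to 81819205. The chromosome 8 region scored 229.77 and 254.32 in the 2 replicates. The imiquimod list held 0 peaks on chromosome Y, so no region there could be shared with it. The depilation list held 10 peaks between 2 and 3 Mb on Y, in the window of these 2 Y regions. Of all 1725 regions in E16.5 alone, 52 were on X or Y.

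Of the 5 best regions in depilation alone, 4 lay near 3 Mb on chromosome 9. They were at 3025260 to 3025684 (score 783.36), 3035672 to 3036142 (724.62), 2999986 to 3000294 (643.48) and 3030117 to 3030304 (510.95). The other was at 98505011 to 98505419 on chromosome 2 (609.59), between the 2 high scoring chromosome 2 peaks given above. All 5 also had a peak in E16.5 replicate 2, scoring between 113.63 and 232.87, and none in replicate 1. They count as depilation regions because the E16.5 set requires both replicates. The imiquimod list held a run of 9 peaks on chromosome 9, from 3000597 to 3037666, none of which overlapped these regions. It therefore had peaks in the same stretch of chromosome 9, at other positions.

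The best regions in imiquimod alone lay on 5 autosomes. They were at 16786275 to 16787002 on chromosome 6, 63936189 to 63936687 on chromosome 2, 6599577 to 6600256 on chromosome 11, 105690379 to 105690918 on chromosome 5 and 4816690 to 4817200 on chromosome 19. Their scores lay between 243.92 and 249.45, and none had a peak in either E16.5 replicate. The chromosome 19 region had the highest fold enrichment of the 5, at 15.51 with 65 tags.

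The imiquimod list also held a dense run of peaks on chromosome 2. With gaps of at most 20 kb, 52 peaks lay in a stretch of 149.7 kb, from 77711665 to 77861350, and covered 16.54% of it. The next largest run of the list had 13 peaks, on chromosome 7 at 38960832 to 38985242. In the chromosome 2 stretch each E16.5 replicate had 1 peak and the depilation list 0. Leaving out this run with chromosomes X and Y changed the regions in all 3 conditions from 750 to 748 and those in imiquimod alone from 6074 to 6002.

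**Figure D4:**
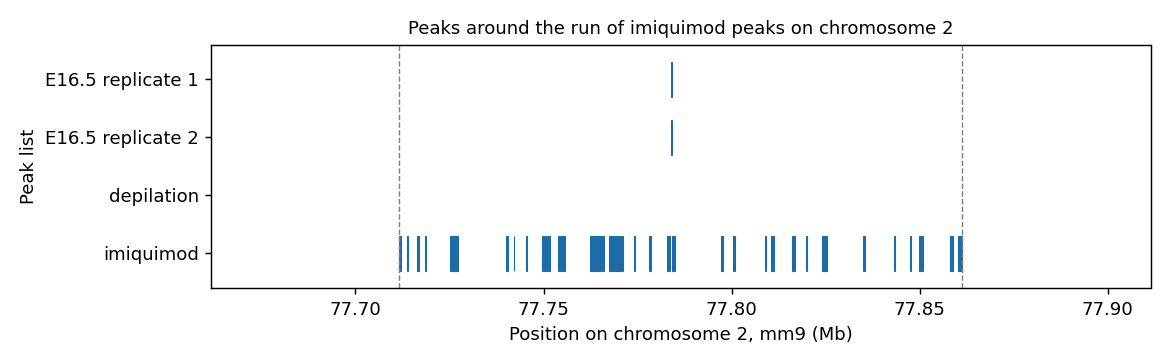
Map of chromosome 2 (mm9, position in Mb on the horizontal axis) with the peaks of each list (rows) drawn to scale, from 50 kb before to 50 kb after the run of imiquimod peaks, whose ends are the dashed lines. The imiquimod list has 52 peaks between them, each E16.5 replicate 1 and the depilation list 0.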

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

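The tests in this part were chosen after the results were seen, apart from that of the upper limit on score as the reason for the few peaks on chromosome X.

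The FDR column of the imiquimod list enters no comparison above, and it carries a signal of its own. In 1541 of its 7974 peaks, or 19.3%, those scoring above 112.74, the FDR rises with score. The pattern to weigh is that the list ends at a score of 249.45 while each other list goes on. A candidate explanation is that an FDR limit of 10% removed the best scoring peaks, since the highest scoring peak left has an FDR of 10%, the highest in the list. Lower depth or enrichment of the imiquimod library alone should keep the best depilation peaks at least as often as weaker ones. Instead, the best 1% were found in the imiquimod list less often than those between the 95th and 99th percentile. They were 11 of 49 against 130 of 192, a difference of -45.3 percentage points (Fisher's exact test, p = 1.18e-08). The same held among depilation peaks on E16.5 reproducible regions, with 9 of 25 against 87 of 121 (Fisher's exact test, p = 0.000995). These tests count peaks as independent, and the best depilation peaks include neighbours on chromosomes 2 and 9. Chromosomes X and Y were not left out. The drop argues against lower depth alone for these peaks. It does not exclude lower depth at other sites, since peaks lost for another reason would give the same drop. Why the FDR rises with score stays open, since the input libraries were not analysed here, and no biological explanation was tested.

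For the run of 52 imiquimod peaks on chromosome 2, use of the same sites in the other samples is argued against. Of its peaks, 0% overlapped a peak of another list, while 40.6% of 5158 imiquimod peaks elsewhere with scores in the same range did. The other lists held 1, 1 and 0 peaks in the whole stretch. The E16.5 peaks, at 77783894 to 77784154 and 77783918 to 77784124, lay just before the run peak at 77784196 to 77784919. Under a looser rule than 1 bp of overlap that site could count as shared. Extra copies of the DNA segment of the run may raise its tags over the whole stretch in the imiquimod library. The peaks covered 16.54% of the run, above the median of 5.94% in the 4 other runs of 5 or more imiquimod peaks but below the highest of them, 23.5%. Its peaks had medians of 74.5 tags, a fold enrichment of 5.925, a width of 432.5 bp and a score of 114.15. Those 5158 peaks had 36 tags, 6.79, 323 bp and 85.49. The peaks of the run thus held more tags and were also wider, and tags were not adjusted for width. Tags between peaks and in the input were not analysed here, so extra copies and a cluster of sites bound after imiquimod cannot be told apart.

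The third pattern is the small number of imiquimod peaks on chromosome X, 25 against 57 after depilation in a list of fewer peaks. Peaks on X were sparse in the other lists too, as given above. Depilation peaks limited to the same maximum score still had 1.11% on chromosome X (Fisher's exact test against the imiquimod list, p = 5.43e-08). That limit removed only 36 depilation peaks and left 53 on X, so it could hardly change the share. How many peaks the imiquimod list lost at high scores is unknown, so the test cannot decide whether their loss is the cause. Male tissue set against female input could lower the X signal relative to input, but it should add peaks on chromosome Y, where the list has 0. The absence of Y decides nothing if that chromosome was left out of the list, so this explanation stays open. The labels give no sex for the animals, and a change in binding on X after imiquimod was not tested.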

How the results depend on the processing

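Each pair of lists overlapped more than after placement in all 38 alternatives tried (placement permutation p = 0.001 in each, circular or, in 4 of them, uniform, the smallest that 1000 placements can give), from 55.8 to 586.4 times the placed mean. Of 166 alternative values, 125 kept their direction and call or, for counts, stayed within 1.5 times. A pair of alternatives was chosen after seeing the data, leaving out peaks above the imiquimod maximum score and leaving out X, Y and the chromosome 2 run, and neither moved a count by over 1.5 times or changed a call, but the former lowered the differences between lists from 7.18 to 4.14 points for depilation peaks and from 3.12 to 1.73 points for imiquimod peaks. Counts fell where fewer peaks were admitted, by construction. With the better scoring 50% of each list, shared peaks numbered 2265 between the E16.5 replicates, 699 between E16.5 and depilation, 791 between E16.5 and imiquimod and 795 between the adult lists. Regions then numbered 397 in all 3 conditions, 792 in E16.5, 1253 in depilation and 2774 in imiquimod alone. With the 1000 best peaks of every list, the same counts were 270, 249, 216 and 207 shared peaks and 79, 614, 605 and 654 regions. With the union of the E16.5 replicates, E16.5 shared 2377 regions with depilation and 2239 with imiquimod, with 1145 regions in all 3 conditions and 13769 in E16.5 alone. Leaving out 1 E16.5 replicate gave 1568 to 2214 regions shared with depilation, 1510 to 2125 shared with imiquimod and 7354 to 8385 in E16.5 alone, the higher value in each case without replicate 2. The shares of E16.5 regions then fell to between 16.2% and 19.1% for depilation and 15.6% and 18.3% for imiquimod, since peaks found in 1 replicate enter. The differences between lists, which were added after the data were seen, changed direction with the better scoring 50% of each list in 2 of 3 cases and in no other alternative tried. The excess of E16.5 regions in depilation over imiquimod by the exact McNemar test was 1.99 points (p = 0.0391) with 50% of the shorter peak covered, 2.02 points (p = 0.0385) with centres within 500 bp and 0.801 points (p = 0.00447) with the union, and -4.88 points with the better scoring 50%. For depilation peaks, the excess in E16.5 over imiquimod was -1.12 points with the better scoring 50%. For imiquimod peaks, the excess in E16.5 over depilation was 1.30 points with the 1000 best peaks. The cause was not tested. No paired analysis was possible because each adult condition has 1 library. Alternatives on distance to genes, gene lists and the motif were not run, for want of an mm9 annotation or sequence. Unknown depth limits each absence, so a region missing from a list was not detected there rather than shown to be unbound.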

Other observations

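The windows of 1 Mb in this part were examined after the data were seen. Some windows held more peaks than random placement gave. In E16.5 replicate 1 the densest autosomal windows were on chromosome 10, with 46 peaks between 80 and 81 Mb and 44 between 79 and 80 Mb. Of 100 random placements of that list on chromosomes other than Y, the fullest window had 18, and the fullest was 17 for E16.5 replicate 2, 11 for depilation and 15 for imiquimod. E16.5 replicate 2 had 29 and 30 peaks in these 2 windows, the depilation list 15 and 8, and the imiquimod list 10 and 12. On chromosome 11, the window between 97 and 98 Mb held 28 peaks in E16.5 replicate 1, 13 in replicate 2, 12 after depilation and 10 after imiquimod, above placement in E16.5 replicate 1 and after depilation.

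Other windows held many peaks in some lists and few in others. The window between 3 and 4 Mb on chromosome 9 held 43 depilation peaks, 19 peaks of E16.5 replicate 2 and 12 imiquimod peaks, but 1 peak of E16.5 replicate 1. The window between 2 and 3 Mb on chromosome Y held 29 peaks of E16.5 replicate 1, 54 of replicate 2 and 10 of the depilation list. Between 38 and 39 Mb on chromosome 7, the imiquimod list had 17 peaks, against 6, 4 and 2 in E16.5 replicate 1, replicate 2 and the depilation list.

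The score relations here were also computed after the data were seen. The scores of peaks shared across conditions were weakly related. Spearman's rho was 0.20 over 1432 regions of E16.5 and depilation, 0.15 over 1364 regions of E16.5 and imiquimod and 0.11 over 1265 peaks of depilation and imiquimod, with permutation p of 1e-05, 1e-05 and 3e-05. These relations, 4 with that of the replicates, are across regions, which are not independent replicates.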
